A study of Mus musculus with 12 samples.

How the data were processed

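RNA from mouse R1 embryonic stem cells, a line derived from a blastocyst, was measured on the paired Affymetrix expression arrays MOE430A (array A) and MOE430B (array B). Each RNA was hybridised once to each array type, so 6 RNAs gave 12 arrays. The labels name 3 RNAs as differentiated, D1 to D3, and 3 as undifferentiated, U1 to U3. The growth protocol in the labels is worded alike for both groups, with bacterial Petri dishes for 5 days, and so does not say how the cultures differed. The labels give the undifferentiated RNAs an estimated purity of 95%. Nothing in the labels states that the RNAs of a group came from separate cultures, so p-values measure the spread between these RNAs, which may be technical.

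The deposited values are MAS5 signal intensities on a linear scale, 1 per probe set and array, as named in the submitters' processing notes. MAS5 is the Affymetrix statistical algorithm that combines the probe pairs of a probe set. Its version, its scaling target, the genome build and any test the authors used are not given in the sources used here. In the deposited tables the 2% trimmed mean of every array lay between 1500.1 and 1500.5, which shows that each array had been scaled to a common mean. Such scaling fixes the average signal of every array and hides any change in total RNA per cell. No detection calls were used here. The experiment settings of each array gave the array lot, the fluidics station and the scan day, which were recoded as numbers.

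The table of array A held 22690 probe sets and that of array B 22575. Gene names came from the platform annotation. On array A, 20380 probe sets had a single gene symbol, 691 had several and 1555 were unnamed here, besides 64 controls. On array B, 14661 had a single symbol, 245 had several and 7605 were unnamed here, besides 64 controls. Of the probe sets with a single symbol, 20351 on array A and 14486 on array B were matched to the RefSeq gene table, and 0 symbols needed updating. Probe sets with several symbols or none were tested and never named. No genome build is named for the arrays, so no coordinates are given.

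Each array was scaled by a single factor to a 2% trimmed mean of 500, signals under 32 were set to 32, and log2 was taken. Probe sets with a mean log2 signal under 6 over the 6 arrays were left out, which removed 4601 on array A and 2167 on array B, and control probe sets were left out of the tests. Differentiated minus undifferentiated differences were tested with limma 3.58.1 (lmFit and eBayes with an intensity trend) in R 4.3.3, separately for each array type, because the tables were normalised separately. Tests were two-sided, with Benjamini-Hochberg adjustment over the probe sets of an array and a threshold of 0.05. A gene was represented by 1 probe set with a single symbol, array A before array B and then the highest mean signal, which does not use the groups. A fold is 2 to the power of the log2 difference, and a floor of 32 understates the change of dim genes.

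The 29 gene lists, of which 10 are main lists, were fixed before the data were examined, from general knowledge of early mouse development and stem cell culture. The lists are naive pluripotency, core pluripotency, postimplantation epiblast, primitive streak and nascent mesoderm, blood and endothelium, cardiac and lateral plate mesoderm, extraembryonic endoderm, neural ectoderm, Hox genes, and epithelial-mesenchymal and matrix genes. The other 19 cover trophoblast, germ line, fibroblast feeder markers, proliferation, cyclin D and CDK inhibitors, imprinted genes, hypoxia and glycolysis, targets of Wnt, of BMP and TGF-beta, of FGF-ERK, of LIF-STAT3 and of p53, retinoid response, DNA methylation and Polycomb, two-cell-like genes, ribosomal proteins, oxidative phosphorylation, cholesterol synthesis, and metallothionein and oxidative stress. Shifts were tested with limma camera at a preset inter-gene correlation of 0.01, on a matrix with each gene once and the columns joined by RNA, with adjustment over the 29 lists. An estimated correlation and cameraPR were alternatives. For each list the members past the threshold over all genes and those adjusted over the list alone were counted.

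The genes named by a rule fixed with the lists are Pou5f1, Nanog and Sox2, the 8 that rose most and the 8 that fell most among called genes whose groups do not overlap, and for each list the called genes of largest difference, 3 for a main list and 2 for another, with the largest called member of the minority direction. That gave 63 genes. Other genes are named only where a count is small or a feature is singled out, and were chosen after their values were seen.

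The fit was tested on simulated data, with 100 probe sets changed 2-fold and 100 changed 4-fold among those of each array. On array A, with 17620 probe sets, 30% of the 2-fold and 72% of the 4-fold changes were recovered, with 9 false calls among 111. On array B, with 19892 probe sets, the recovered shares were 0% and 1%. The number of arrays limits the precision. Alternatives covered the scaling, the floor, the filter, the variance model, the adjustment, the choice of probe set, a replicate block, the array lot or fluidics station as a block, and each RNA left out in turn. A further alternative, array A without D1 and array B without U2, was chosen after seeing the data. Exact permutation tests of 3 against 3 cannot give p under 0.1. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.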

Results

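Transcript levels were compared between R1 mouse embryonic stem cells labelled as differentiated into embryoid bodies, which are aggregates in which stem cells begin to specialise, and the same line labelled undifferentiated. The growth protocol in the labels is worded alike for both, so how the cultures differed rests on these names. The comparison asks which genes differ between these states. Each group had 3 RNAs, each measured on array A and array B. The median deposited signal of an array lay between 674.6 and 820.7 on array A and between 882.1 and 1047.6 on array B. On array A, D1 correlated least with the other arrays (median r = 0.843), and on array B, U2 did (median r = 0.637). The log2 ratio of the 3' to the 5' actin control probe sets, a sign of RNA integrity, was 0.34 ± 0.31 (SD, n = 3) in differentiated and 0.22 ± 0.09 (SD, n = 3) in undifferentiated RNAs on array A, with D1 at 0.70. On array B it was 0.42 ± 0.23 (SD, n = 3) and 0.24 ± 0.27 (SD, n = 3), with D1 at 0.68. With 3 RNAs a group, an exact permutation test of this ratio cannot reach a p under 0.1.

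In the differentiated RNAs, Ttr, Spink1 and Apoa1, from the list of extraembryonic endoderm genes, were 8.91-fold to 18.9-fold higher, while Lefty1, Tdgf1 and Klf4, from the pluripotency lists, were 3.12-fold to 4.94-fold lower. Of 16461 genes tested, 152 rose and 191 fell (343 in all, limma with Benjamini-Hochberg adjustment). A difference of at least 2-fold was reached by 220 of them, of which 100 rose and 120 fell. Of all tested genes, 18.41% had groups whose arrays did not overlap, where 10% would by chance. For 204 changed genes at least 2 probe sets were tested, and a second probe set was called in the same direction for 47 and in the opposite direction for 0. On array A, 518 of 18025 probe sets passed (237 rose, 281 fell), and 2847 had an unadjusted p under 0.05. Array B gave 4 of 20344, with 1066 at an unadjusted p under 0.05, which is 5.24% of those tested. The array B probe sets were those of Irs4 and Clic6, which rose, and of Igfbp3 and Rbmxl2, which fell, and Irs4 and Clic6 are named after their values were seen. The array A probe set of Irs4 had a log2 difference of 0.07 ± 0.64 (SE), against 3.43 on array B, so the probe sets of this gene disagreed. All but 1 of the 343 changed genes were represented by array A.

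**Figure D1:**
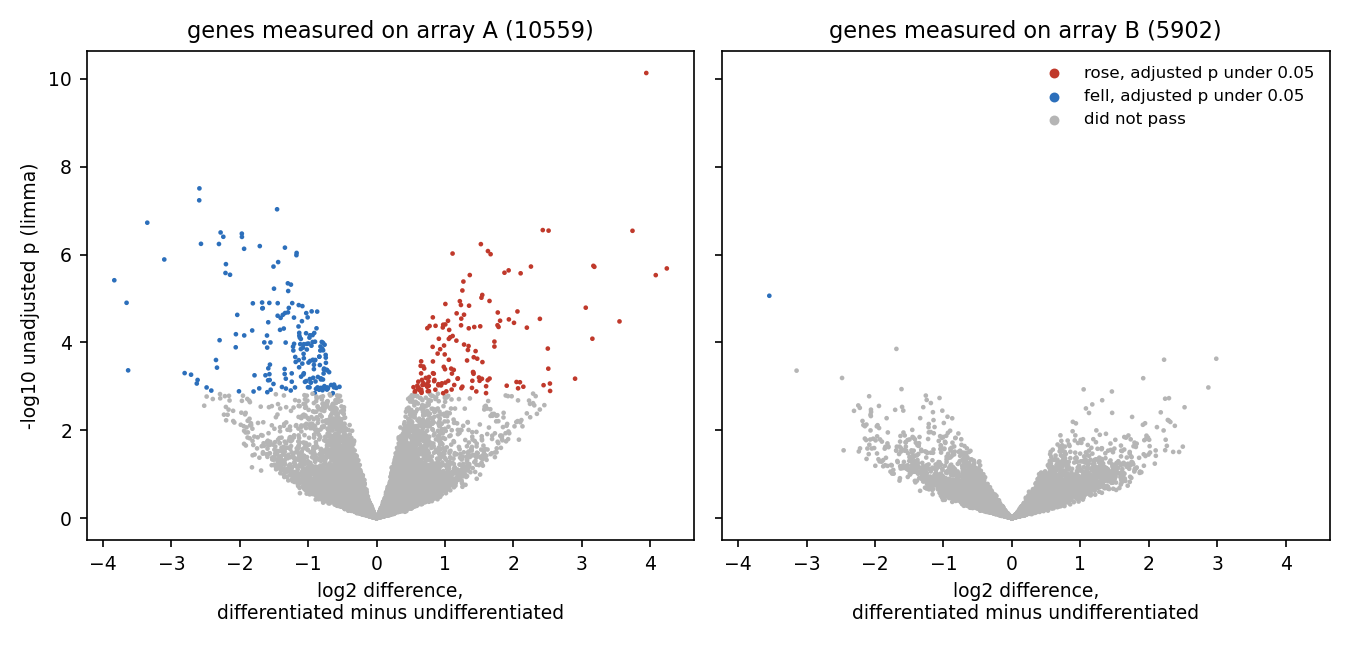
Each point is a gene, with its log2 difference (differentiated minus undifferentiated) on the x axis and the negative log10 of the unadjusted limma p on the y axis, for the 10559 genes represented by array A and the 5902 represented by array B. Genes past an adjusted p of 0.05 are coloured, 342 on array A and 1 on array B.

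Among the genes with the largest increases, Ttr, the carrier of thyroid hormone and retinol, rose from a log2 signal of 6.05 ± 0.93 to 10.29 ± 0.51 (SD, n = 3 each, limma adjusted p = 0.000908). Lhx1, a homeobox gene of the organiser and anterior visceral endoderm, rose by 4.08 ± 0.46 on the log2 scale (SE, adjusted p = 0.0011), with 2 of its 3 undifferentiated arrays at the signal floor. Spink1, a secreted trypsin inhibitor, went from 8.59 ± 0.11 to 12.54 ± 0.23 (SD, n = 3 each) and had the smallest adjusted p of all genes, 1.32e-06. Amot, which encodes the junction protein angiomotin, rose by 3.74 ± 0.33 (SE, adjusted p = 0.000459). Car14, a carbonic anhydrase, Ptpn13, a tyrosine phosphatase, Mogat2, an acyltransferase of triglyceride synthesis, and Apoa1, the main protein of high-density lipoprotein, rose by 3.55, 3.18, 3.17 and 3.15 (adjusted p between 0.000855 and 0.00838). At the signal floor lay 2 undifferentiated arrays for Car14 and 1 each for Ttr and Apoa1, so their differences are not exact. The probe sets of Ttr, Apoa1 and Car14 are of kinds that can bind related transcripts.

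Among the genes with the largest decreases, S100a4, a calcium-binding protein of fibroblasts, fell from a log2 signal of 10.13 ± 0.27 to 6.29 ± 0.97 (SD, n = 3 each, limma adjusted p = 0.00136). Bgn, the proteoglycan biglycan, had a difference of -3.63 ± 0.73 (SE, adjusted p = 0.0243), and Pcolce, an enhancer of procollagen processing, one of -3.35 ± 0.29 (SE, adjusted p = 0.000459). Mgp, matrix Gla protein, fell by 2.71 (adjusted p = 0.0282), and Acta1, a muscle actin, fell by 2.81 (adjusted p = 0.0272). Igfbp3, a binding protein of insulin-like growth factors, fell by 3.10 ± 0.32 on array A (SE, adjusted p = 0.000727), and its array B probe set fell by 1.88. Ltb, a lymphotoxin, fell by 3.65 (adjusted p = 0.00313). Rbmxl2, an RNA-binding protein known from testis, fell by 3.55 on array B (adjusted p = 0.044). At the signal floor lay 1 differentiated array each for Ltb, Bgn and Mgp, and 2 for Acta1.

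**Figure D2:**
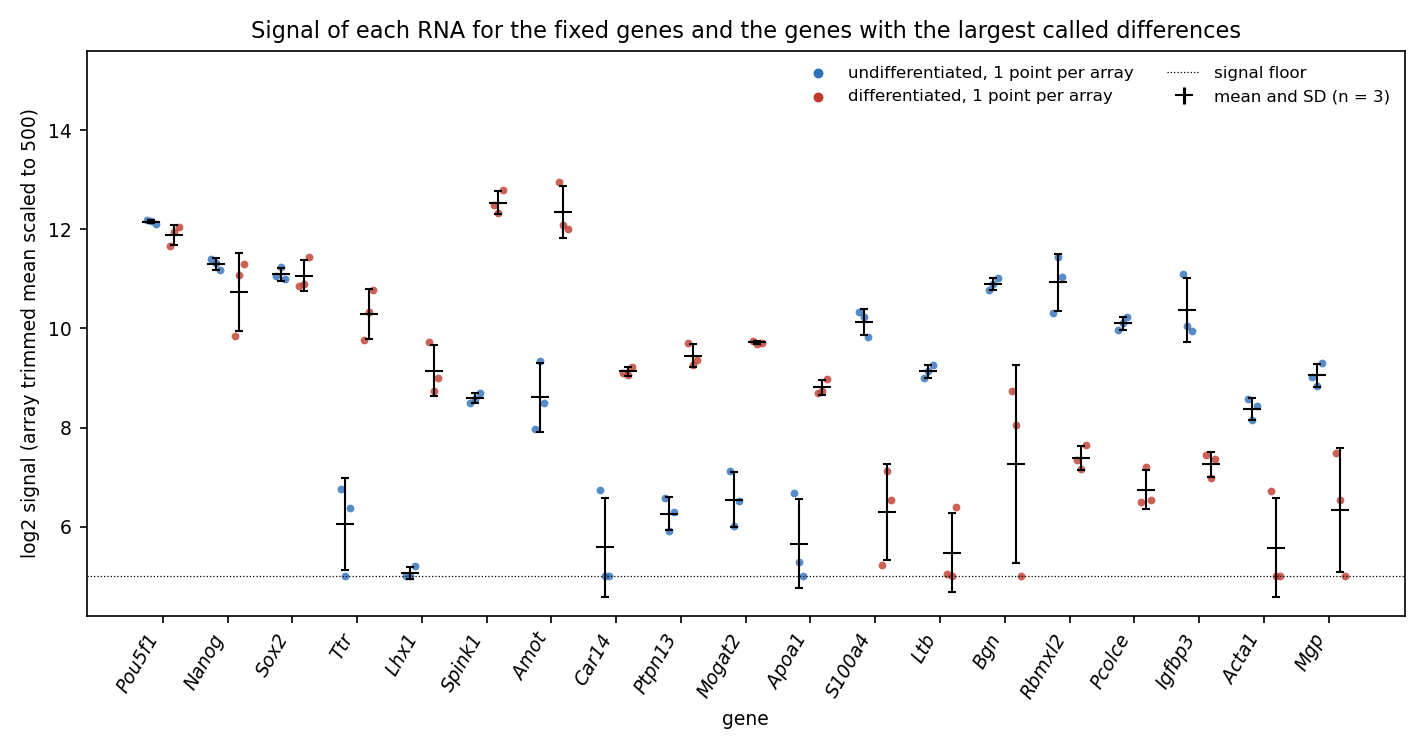
Log2 signal (y axis) of each RNA for the 3 genes fixed beforehand and the 16 genes with the largest called differences (x axis), with 1 point per array, black bars for the mean and SD of 3 arrays, and a dotted line at the signal floor of 32. The groups of Nanog and Sox2 overlap and those of Pou5f1 lie close together without overlap, and the other 16 genes were chosen by a rule that requires no overlap.

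The 3 central pluripotency factors did not pass the test. Pou5f1 had a log2 signal of 11.88 ± 0.20 in differentiated and 12.15 ± 0.04 in undifferentiated RNAs (SD, n = 3 each, limma adjusted p = 0.352). Nanog had 10.74 ± 0.79 against 11.30 ± 0.11 (adjusted p = 0.43), with D1 at 9.84 and a log2 difference that went from -0.56 to -0.11 without D1, and Sox2 had 11.06 ± 0.32 against 11.09 ± 0.13 (adjusted p = 0.961). The core pluripotency list was lower as a group (median log2 difference -0.57, camera adjusted p = 2.56e-08), with a mean, set against the undifferentiated mean, of -1.05 in D1, -0.62 in D2 and -0.58 in D3, and 6 of its 22 genes fell, 0 rose, and 16 did not pass (11 fell and 1 rose adjusted over the list alone). The members that fell most were Lefty1, an inhibitor of Nodal signalling (-2.30 ± 0.22, SE), Tdgf1, a Nodal coreceptor (-2.04 ± 0.29, SE), and Gdf3, a ligand of the same family (-1.94 ± 0.19, SE). For this list adjusted p = 0.178 with an estimated correlation, the highest over its alternatives, of which the lowest was 2.37e-14.

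Naive pluripotency genes, which mark the state before implantation, were lower (median -0.62, camera adjusted p = 2.13e-05). Of 22, 2 fell, 0 rose and 20 did not pass (4 fell adjusted over the list alone). The 2 were the Krüppel-like factors Klf4 (-1.64 ± 0.27, SE) and Klf5 (-1.29 ± 0.16, SE). The list's mean, set against the undifferentiated mean, was -0.99 in D1, the RNA that correlated least on array A, and -0.36 in both D2 and D3. With an estimated correlation the adjusted p = 0.262, the highest over the alternatives, and the lowest was 1.54e-06. Targets of LIF and STAT3, the signal that maintains mouse stem cells in culture, had a median of -0.84 (camera adjusted p = 1.63e-08), and 7 of 20 fell, 0 rose and 13 did not pass (12 fell adjusted over the list alone). Icam1, an adhesion molecule, had a difference of -2.06 ± 0.35 (SE, adjusted p = 0.0107), beside Klf4 and Klf5. Of the 20, 7 are also in another list. The adjusted p = 0.078 with an estimated correlation, and the lowest over the alternatives was 3.35e-12.

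Genes of the postimplantation epiblast were higher (median 0.49, camera adjusted p = 0.00129), with a mean of 0.52 in D1, 0.23 in D2 and 0.32 in D3 against the undifferentiated mean. Of 19 measured, 5 rose, 0 fell and 14 did not pass (7 rose adjusted over the list alone). Those that rose included Sall2, a zinc finger factor (1.39 ± 0.32, SE), Dnmt3b, a de novo DNA methyltransferase (1.23 ± 0.19, SE), and Tead2, a partner of YAP (1.09 ± 0.22, SE). Of the 19, 13 lay above 0 and 6 below. Otx2 (1.29, limma adjusted p = 0.0758) and Fgf5 (1.08, limma adjusted p = 0.247) did not pass. Pou3f1 (-0.21), Fgf15 (-1.28) and Wnt8a (-1.81) lay below 0 without passing. These members were picked after their values were seen. The adjusted p = 0.128 with an estimated correlation, the highest over its alternatives, and the lowest was 1.75e-05.

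The lists of primitive streak, mesoderm, neural and Hox genes did not pass. For primitive streak and nascent mesoderm the median was 0.37 (camera adjusted p = 0.181), which turned to -0.12 with the batch described below as a block (adjusted p = 0.238, within a range of 0.0661 to 0.409 over its alternatives), and 2 of 24 rose, 1 fell and 21 did not pass (3 rose and 1 fell adjusted over the list alone). Those were Lhx1, Aplnr, the apelin receptor (2.39 ± 0.35, SE, limma adjusted p = 0.00459), and Fgf17, which fell (-1.60 ± 0.26, SE, adjusted p = 0.00761). Of 24 blood and endothelium genes 0 changed, also 0 adjusted over the list alone (median -0.07, camera adjusted p = 0.547). Of 29 cardiac and lateral plate genes 0 rose and 1 fell, the smooth muscle actin Acta2 (-1.23 ± 0.16, SE), against 2 and 2 adjusted over the list alone, and the median (-0.01) and the mean (0.20) differed in sign (camera adjusted p = 0.629). Neural ectoderm had a median of -0.12 (camera adjusted p = 0.547), and of its 22 genes Sox11 (1.54 ± 0.33, SE) and Msi1 (1.40 ± 0.30, SE) rose and Stmn2, a stathmin of neurons, fell (-0.79 ± 0.14, SE), against 2 that rose and 2 that fell adjusted over the list alone. None of 22 Hox genes changed, nor did any adjusted over the list alone (0 each, median 0.09, camera adjusted p = 0.758).

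Extraembryonic endoderm genes were higher, with a median of 0.41 and a mean of 0.79 (camera adjusted p = 2.13e-05). Of 32 measured, 10 rose, 1 fell and 21 did not pass (13 rose and 2 fell adjusted over the list alone). Besides Ttr, Spink1 and Apoa1, the genes that rose were Srgn, Foxa2, Rbp4, Gata6, Sox17, Dab2 and Col4a1, by 0.9965 to 2.44 on the log2 scale, and these 7 are named after their values were seen. Gata6, Sox17 and Foxa2 are transcription factors of endoderm. Nid1, a basement membrane protein, fell (-1.57 ± 0.32, SE, limma adjusted p = 0.0277). Of the 32, 23 lay above 0 and 9 below. Amn (0.02), Cubn (0.05) and Hnf4a (0.21) lay near 0. Lamb1 (-0.60), Lamc1 (-0.61) and Thbd (-1.44) lay below 0 without passing. These members too were picked after their values were seen. The mean of the list was higher in each of the 3 differentiated RNAs than in any undifferentiated one. The adjusted p = 0.0965 with an estimated correlation, the highest over its alternatives, and the lowest was 2.73e-13.

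Epithelial-mesenchymal and matrix genes were lower (median -0.71, camera adjusted p = 6.01e-11). Of 32, 9 fell, 0 rose and 23 did not pass (15 fell adjusted over the list alone). Timp1 (-1.97 ± 0.18, SE) and Timp2 (-1.82 ± 0.28, SE) encode inhibitors of matrix metalloproteinases, and Ccn2 (-1.71 ± 0.17, SE) encodes connective tissue growth factor. The adjusted p = 0.078 with an estimated correlation, and the lowest over the alternatives was 3.57e-20. Fibroblast feeder markers, a list fixed as a sign of other cells in the culture, were lower too (median -1.10, camera adjusted p = 4.16e-08). Of 26, 8 fell, 0 rose and 18 did not pass (12 fell adjusted over the list alone), with S100a4 and Bgn the furthest. The list's mean set against the undifferentiated mean was -0.78 in D1, -1.03 in D2 and -1.60 in D3. With an estimated correlation the adjusted p = 0.178, the highest over its alternatives, and the lowest was 1.41e-19.

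Hypoxia and glycolysis genes had the lowest p of the 29 lists at the preset correlation, though not with an estimated one (median 0.81, camera adjusted p = 9.78e-14). Of 28, 9 rose, 0 fell and 19 did not pass (18 rose adjusted over the list alone). Gys1, the muscle form of glycogen synthase, rose by 2.51 ± 0.50 (SE, adjusted p = 0.0229), and Ddit4, an inhibitor of mTORC1 induced by low oxygen, rose by 1.77 ± 0.27 (SE, adjusted p = 0.00574). The list's mean set against the undifferentiated mean was 0.82 in D1, 0.67 in D2 and 0.62 in D3. The adjusted p = 0.0784 with an estimated correlation, the highest over its alternatives, and the lowest was 7.03e-22.

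**Figure D3:**
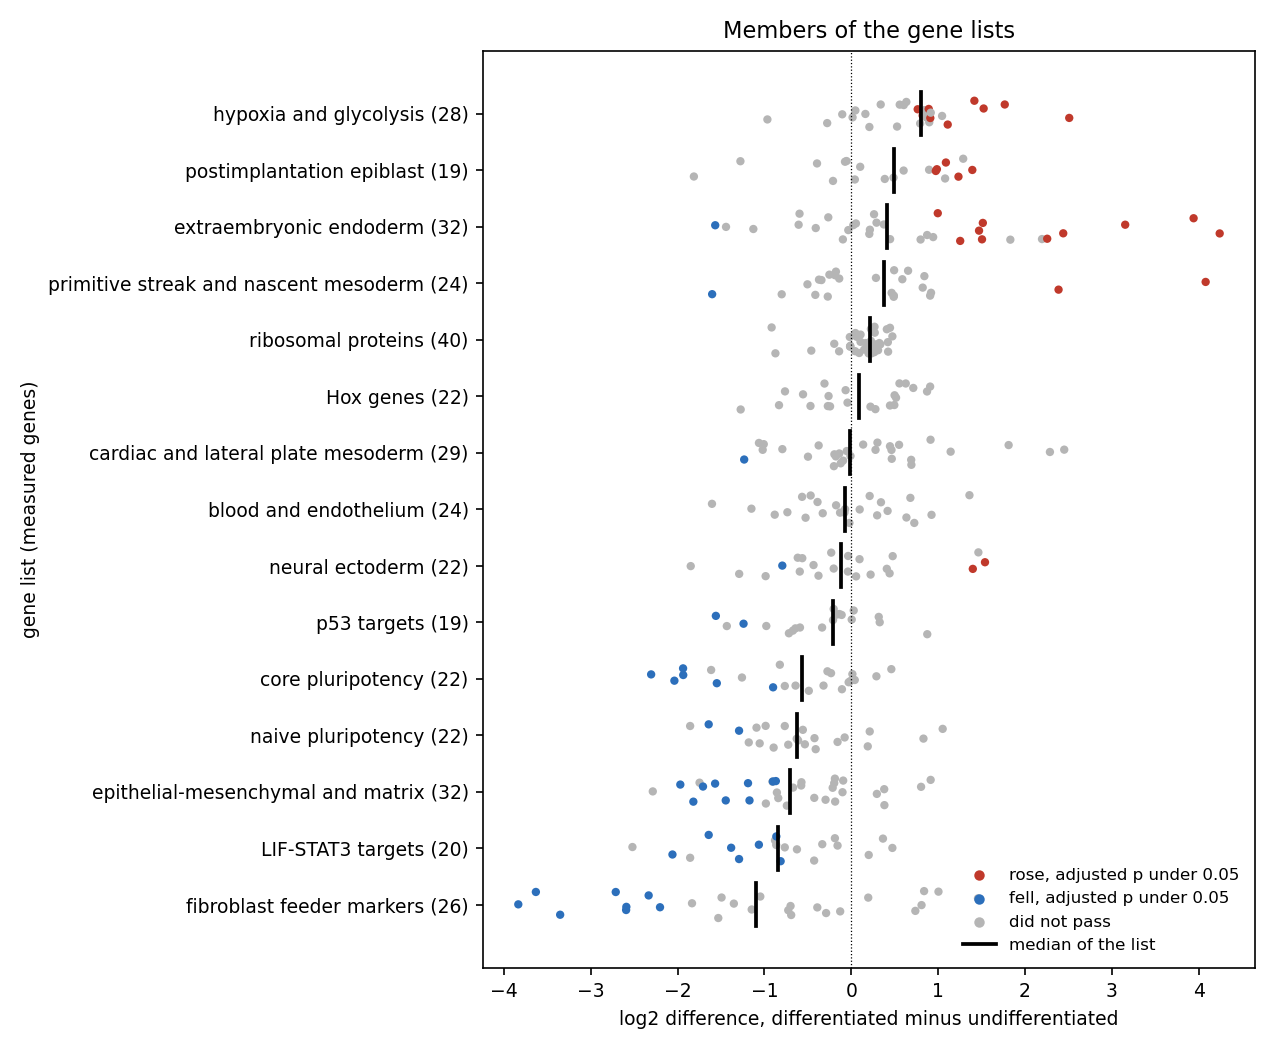
Log2 difference (x axis, differentiated minus undifferentiated) of each measured gene in the 10 main lists and in the other lists past the threshold (y axis, with the number of genes), coloured where the gene passed an adjusted p of 0.05. Vertical bars are list medians, from -1.10 for fibroblast feeder markers to 0.81 for hypoxia and glycolysis, and the ribosomal protein median of 0.21 goes to -0.00058 with quantile normalisation.

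In all, 10 of the 29 lists passed, 4 higher and 6 lower, and with an estimated correlation 0 did (lowest adjusted p = 0.078), while cameraPR gave 12. Without a filter on dim probe sets 14 passed, 6 higher and 8 lower, and leaving out each RNA in turn gave 10 to 12. On array A the fluidics station divided the arrays exactly as the groups did, so station and group cannot be told apart there. Array lot 1 held D1 to D3 and U1, and lot 2 held U2 and U3. On array B, with a single lot, 1 station held D1 to D3 and U1. With this batch as a block, where U1 alone sets the undifferentiated level, 76 genes were called (42 rose, 34 fell), 75 of them at least 2-fold, with 106 probe sets on array A (65 rose, 41 fell) and 0 on array B. Of the 60 called genes named by the rule, 19 were called with the block, and all 60 had the same direction. That direction was fixed beforehand, because the groups of these genes do not overlap and the block sets D1 to D3 against U1. With the block 14 lists passed, 8 higher and 6 lower. They were the same 10 and 4 that did not pass without it, trophoblast (adjusted p = 0.0451), BMP and TGF-beta targets (0.0311), retinoid response (0.0495), and DNA methylation and Polycomb (0.0223). The 10 had adjusted p from 9.28e-15 for hypoxia and glycolysis to 0.00899 for p53 targets. The blocked p was 0.00368 for naive pluripotency, 3.02e-05 for core pluripotency, 3.22e-05 for LIF-STAT3 targets, 0.00338 for postimplantation epiblast, 3.22e-05 for extraembryonic endoderm, and 4.50e-08 for both matrix and fibroblast lists. Within lot 1, set against U1, the array A medians were -0.51 for naive and -0.41 for core pluripotency, -0.81 for LIF-STAT3 targets, 0.57 for postimplantation epiblast, 0.51 for extraembryonic endoderm, -0.64 for matrix genes, -1.41 for fibroblast markers and 0.84 for hypoxia and glycolysis. For naive pluripotency the median against U1 was -1.03 in D1, -0.48 in D2 and -0.08 in D3, so D3 hardly differed from U1.

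The number of calls also moved by over 1.5 times with the variance model and the filter, to 56 genes without the intensity trend and 120 without a filter on dim probe sets. It fell to 209 with median centring, 212 with adjustment over both arrays, 227 without D2, 209 without D3, 148 without U2 and 129 without U3. Of the 60 called genes named by the rule, 15 had a difference over 1.5 times smaller under an alternative that also ended the call. Among those named above, another probe set gave 2.17 for Ttr (adjusted p = 0.715, the highest over alternatives that began at 0.000518), 2.47 for Lhx1 (0.057, from 0.000764), 0.93 for Aplnr (0.563, from 0.00337), 0.92 for Sox11 (0.856, from 0.0252) and 1.31 for Gys1 (0.43, from 0.0123). The other Ttr probe set lies on array B, where 4 of 20344 probe sets passed. Its lost call alone does not show that the probe sets disagree. The lot or station block gave 0.91 for Sall2 (adjusted p = 0.54, from 0.0286), 0.67 for Tead2 (0.402, from 0.00692) and -1.17 for Timp2 (0.163, from 0.0023). For Ptpn13 the lowest value was 0.71 (adjusted p = 0.645, from 0.000517), in the fit without D2, where the rule picks another probe set. The probe set named above gave 3.27 there (adjusted p = 0.00736) and 3.01 to 3.34 without each RNA in turn.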

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

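The test of U2 on array B was chosen after its result was seen, and the other tests before theirs, though after the list medians and the largest gene differences. On array A, the bacterial hybridisation controls, which are added RNAs outside the comparison, had in D1 a mean log2 signal 0.7083 above the highest undifferentiated array. D1 also had the highest 3' to 5' actin ratio of array A, 0.70 on the log2 scale.

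The first pattern is the lower level of fibroblast feeder markers in the differentiated RNAs, with a median of -1.10 over 26 genes. The array lot is argued against, because within lot 1, set against U1, the median was -1.4098, whereas the fluidics station of array A cannot be told apart from the group. Fibroblasts in the undifferentiated cultures stay open as a hypothesis. The collagens Col1a1, Col1a2 and Col3a1, abundant in fibroblasts, had a median of -1.5677. Their scaled signals were 357.4, 1219.4 and 297.3 in undifferentiated and 224.6, 411.4 and 88.6 in differentiated RNAs. Col1a1 (limma adjusted p = 0.397) and Col3a1 (limma adjusted p = 0.232) did not pass. These collagens belong to the epithelial-mesenchymal and matrix list, whose lower median had already been seen. Their fall is thus not independent support. Of the list genes 6 lay above 0 and 0 of them passed, among them Islr (1.4594, adjusted p = 0.288), Dcn (0.74, adjusted p = 0.841) and Lum (0.84, adjusted p = 0.536), picked after their values were seen. Of the 26 genes, 25 had a differentiated mean above the filter and 0 are in another list. The filter on the mean of the 6 arrays partly fixes the first count, and neither count shows which cells express the genes. Lower expression of these genes by the stem cells themselves may equally hold and was not tested.

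The second pattern is the higher level of hypoxia and glycolysis genes, with a median of 0.81 over 28 genes. The D1 library as the sole source is argued against by a median of 0.6274 without it, and the array lot by a median of 0.8402 within lot 1. A response to low oxygen, which may arise inside cell aggregates, stays open as a hypothesis. The 13 members taken as outside the glycolytic chain had a median of 0.8432. Their mean was higher in each differentiated RNA than in any undifferentiated one. They belong to the list whose rise had already been seen. These values were thus partly set beforehand and cannot decide the hypothesis. Gys1, Pdk1 and Ero1a were counted neither among the 13 nor in the glycolytic chain. Of these 13, 3 rose past the threshold and 0 fell, and Vegfa did not pass (0.53, limma adjusted p = 0.343). Of the 28 list genes 25 lay above 0 and 3 below, among them Adm (-0.97) and Car9 (-0.28). Vegfa, Adm and Car9 were picked after their values were seen. The 12 measured genes of the glycolytic chain had a median of 0.79, and the move of the 13 others argues against a change in glycolysis alone, though not against other causes that raise both. The fluidics station of array A cannot be told apart from the group here either.

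The third pattern is the small number of calls on array B, 4 against 518 on array A. The outlying U2 array as the whole cause is argued against, because without U2 array B gave 2 calls and array A 214. A larger spread between replicates on array B may account for it: with all arrays the median residual SD was 0.66 on array B and 0.37 on array A, a ratio of 1.7645, and without U2 it was 0.53 and 0.38, a ratio of 1.3886, so U2 is part of that spread. In the simulated data, array B recovered 0% of 2-fold and 1% of 4-fold changes. Of the 100 probe sets present on both arrays, 5 were called on array A and 0 on array B. The few calls on array B therefore do not show that few of its genes changed. Why array B varied more was not tested, and no biological explanation was tested.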

How the results depend on the processing

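The alternative without D1 on array A and U2 on array B was chosen after seeing the data, and the others before. Counts are given as probe sets on array A, probe sets on array B, and genes, against 518, 4 and 343. Median centring gave 307, 2 (both rose) and 209, and no filter gave 194, 1 and 120, with 86 genes at least 2-fold against 220. Without the intensity trend the counts were 97, 0 and 56, all 56 at least 2-fold, and with adjustment over both arrays they were 319, 10 and 212. With the lot or station as a block they were 106, 0 and 76, with 75 at least 2-fold. Array B gave 2 calls with a floor of 10, 1 with a floor of 100, and 2 with the robust model. Without D1 on array A and U2 on array B, array B gave 2, array A 497, and there were 326 genes, 205 at least 2-fold. For these moves the cause was not tested, apart from the joint adjustment, which pools an array with few small p-values. Leaving out each RNA in turn gave 190 to 497 probe sets on array A, 0 to 2 on array B, 129 to 326 genes and 113 to 205 at least 2-fold, with fewer arrays in the fit. The lowest came without U3 (129 genes, 126 of them shared with the 343) and without U2 (148, 142 shared), and D2 and D3 left 227 and 209.

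All 60 called genes named by the rule kept their direction under every alternative run, and 9 of them were called under each one that left out no single RNA. The groups of all 343 changed genes did not overlap, so for the same probe set most alternatives could not turn a direction. Only another scaling or another probe set could. Of the 343 changed genes, 337 kept their sign with the probe set of highest signal on either array and 330 with the probe set of median difference. Of the 343, 204 had at least 2 tested probe sets, and the others had none to switch to.

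With an estimated correlation 0 lists passed, with adjusted p of 0.07804 for matrix genes and LIF-STAT3 targets, 0.07837 for hypoxia and glycolysis, 0.09654 for extraembryonic endoderm, 0.1278 for postimplantation epiblast, 0.1783 for core pluripotency and fibroblast markers, 0.2624 for naive pluripotency, 0.2663 for ribosomal proteins and 0.3351 for p53 targets. That setting replaces the preset correlation by one estimated from 6 RNAs. The shift of ribosomal proteins went to about 0 with quantile normalisation (adjusted p = 0.7763), and p53 targets had adjusted p = 0.07 without D1 on array A and U2 on array B. For both the cause was not tested.

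Same-numbered RNAs deviated together with r of 0.157, 0.012 and 0.073 on array A and 0.183, 0.097 and 0.118 on array B. RNAs of different numbers had r from -0.145 to 0.090 on array A and from -0.144 to 0.033 on array B. Not every same-numbered pair was over 0.1, which does not decide whether the numbers pair the RNAs. With the replicate block 466 genes were called, 335 of them shared with the 343, with 724 probe sets on array A and 1 on array B. On array B every RNA correlated best with its own number, which on array A did not hold, a hint from the data and not from the design.

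In the real grouping 518, 4, 343 and 220 calls and 10 lists passed. The other splits all gave 0 calls, yet each of them passed between 1 and 6 lists. The real split was the 1 of 10 that gave as many calls and lists, and 10 splits cannot give a share under 0.05. At the preset correlation, camera thus passed lists also where the groups were mixed. Those splits are not balanced between the states, so they keep part of the group difference. Low signal limits dim genes: 8.57% to 15.7% of array A values and 2.98% to 6.61% of array B values lay at the floor. The scaling to a common mean also sets these shares, so they do not show that array B held fewer dim genes. The bacterial hybridisation controls had a mean log2 signal of 13.60 in differentiated and 13.26 in undifferentiated RNAs on array A. On array B they had 14.67 and 14.69.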

Other observations

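Chosen after the result was seen were the division into visceral and parietal endoderm and, for the probe sets on both arrays, the correlations without U2 and within a station. Among signalling genes, Cyp26a1, the enzyme that degrades retinoic acid, rose by 3.06 ± 0.42 on the log2 scale (SE, limma adjusted p = 0.00359), and Crabp2, a retinoic acid binding protein, rose by 2.10 ± 0.46 (SE, adjusted p = 0.0363). They were the 2 of 15 retinoid response genes that changed (2 also adjusted over the list alone), and the list did not pass, with a median of -0.01 and a mean of 0.36 of opposite sign (camera adjusted p = 0.442). With the lot or station as a block, where U1 alone sets the undifferentiated level, the list's median was 0.39. U1 was low for this list, with a mean of -0.24 against 0.20 in U2 and 0.03 in U3. Over the alternatives the camera adjusted p of the list went up to 0.673. The BMP targets Id1 (1.53 ± 0.20, SE) and Id3 (1.28 ± 0.18, SE) rose, 2 of 19 in a list that did not pass (median 0.30, adjusted p = 0.207, 4 rose and 3 fell adjusted over the list alone). With the block, again set by U1 alone, the BMP and TGF-beta list had a median of 0.31. Its mean was -0.19 in U1, 0.07 in U2 and 0.13 in U3. Over the alternatives its camera adjusted p went up to 0.543. Among 17 Wnt targets, Dkk1, a Wnt inhibitor, rose by 2.05 ± 0.44 (SE), and Notum (-1.45 ± 0.21, SE) and Ccnd1 fell (median 0.27, adjusted p = 0.793, 2 and 2 adjusted over the list alone). Of 19 FGF-ERK targets only Junb passed (-1.06 ± 0.22, SE), also adjusted over the list alone (1 fell, median -0.28, list adjusted p = 0.0972).

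Imprinted genes moved both ways: 5 of 25 rose and 2 fell (6 and 4 adjusted over the list alone). Grb10 (1.63 ± 0.16, SE) and Peg3 (1.41 ± 0.29, SE) rose and Phlda2 fell (-1.08 ± 0.19, SE). The list did not pass, with a median of -0.02 and a mean of 0.08 (adjusted p = 0.506). Cell cycle genes showed no shift. Of 30 proliferation genes Bub1 rose (0.90 ± 0.20, SE) and Ccne1 fell (-0.93 ± 0.17, SE), against 2 and 2 adjusted over the list alone (median 0.01, adjusted p = 0.629). Ccnd1 (-1.07 ± 0.19, SE) and Mycn (-0.76 ± 0.17, SE) were the 2 of 18 cyclin D and CDK inhibitor genes that fell, with 3 adjusted over the list alone (median -0.15, adjusted p = 0.22). The p53 targets were lower (median -0.21, adjusted p = 0.00226, and adjusted p = 0.335 with an estimated correlation, the highest over alternatives that began at 0.000407), and 2 of 19 fell (4 adjusted over the list alone), Perp (-1.56 ± 0.30, SE) and Plk2 (-1.24 ± 0.25, SE). Its blocked p was 0.00899, and its median within lot 1 was -0.35. The list's mean was -0.64 in D1 against -0.26 in D2 and -0.28 in D3, and without D1 on array A and U2 on array B the list did not pass (adjusted p = 0.07). With another probe set the differences came to 0.09 for Bub1 (adjusted p = 0.969, the highest over alternatives that began at 0.022), -0.43 for Ccne1 (0.859, from 0.00804), -0.81 for Plk2 (0.841, from 0.0185) and 1.19 for Dkk1 (0.841, from 0.0253). The other probe sets of Ccne1 and Plk2 lie on array B, where 4 of 20344 probe sets passed. A lost call there does not alone show that the probe sets disagree. With the lot or station block the differences came to 0.74 for Peg3 (0.45, from 0.00101) and, in the list below, to -0.60 for Jarid2 (0.229, from 0.00424).

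Of 30 genes of DNA methylation and Polycomb, Dnmt3b rose and Jarid2 fell (-0.90 ± 0.15, SE), and 6 rose and 2 fell adjusted over the list alone (median 0.22, adjusted p = 0.0894). The list passed with the block (adjusted p = 0.0223) and in 5 of 24 alternatives, which ranged from 0.0039 to 0.446. Krt18, a keratin of simple epithelia, was the 1 of 13 trophoblast genes that rose (1.23 ± 0.17, SE), with 1 adjusted over the list alone (median 0.46, adjusted p = 0.0972). The trophoblast list passed with the block (median 0.11, adjusted p = 0.0451) and in 6 of 24 alternatives, which ranged from 0.00288 to 0.429. Ifitm3 was the 1 of 16 germ line genes that fell (-1.34 ± 0.13, SE), with 1 adjusted over the list alone (median -0.04, adjusted p = 0.361). Of 22 metallothionein and oxidative stress genes, Gpx1 (-1.45 ± 0.12, SE) and Gsto1 (-0.9955 ± 0.19, SE) fell and Mt1 rose (0.97 ± 0.23, SE), against 6 that fell and 1 that rose adjusted over the list alone (median -0.24, adjusted p = 0.0582). That list passed in 6 of 24 alternatives, whose camera adjusted p ranged from 0.00387 to 0.666. Hmgcs1 was the 1 of 19 cholesterol synthesis genes that rose (0.75 ± 0.17, SE), with 3 and 1 adjusted over the list alone, a median of -0.02 and a mean of 0.10 (adjusted p = 0.753). None of 6 two-cell-like genes changed (0 adjusted over the list alone, median 0.16, adjusted p = 0.572). Oxidative phosphorylation had 0 changed genes of 55, with 1 that rose and 2 that fell adjusted over the list alone (median -0.01, adjusted p = 0.687). Ribosomal proteins had 0 of 40 changed, also adjusted over the list alone. Their mean was 0.19 in D1 and 0.08 in D2 and D3, and their median was 0.21 (adjusted p = 0.000104, blocked p 0.00123, median within lot 1 of 0.19), which went to -0.00058 with quantile normalisation (adjusted p = 0.776), the highest over alternatives that began at 3.97e-05, and with an estimated correlation adjusted p = 0.266.

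A hypothesis was that the rise of extraembryonic endoderm genes may lie in visceral more than in parietal endoderm, the layers that line the embryo and the yolk sac cavity. The mean of 14 visceral genes minus the mean of 14 parietal genes was higher by 1.4374 on the log2 scale in differentiated RNAs (-0.05 ± 0.48 against -1.49 ± 0.36, SD, n = 3 each, exact permutation test, two-sided, p = 0.1, the smallest possible). The division was written when the differences of Ttr, Spink1, Apoa1, Foxa2 and Srgn had been seen. Without these 5 genes, with 10 visceral and 13 parietal genes left, the difference was 0.8389 (exact permutation p = 0.2), and D3 lay below U1, so the data do not decide this hypothesis. Of the visceral genes 5 rose and 0 fell, and of the parietal genes 2 rose and 1 fell, and without the 5 genes 1 visceral gene rose and 1 parietal gene rose and 1 fell. The division of the list into these layers is textbook knowledge and some genes are active in both.

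The 100 probe sets present on both arrays repeat the comparison on the same RNAs. Their differences correlated across probe sets, which are not independent replicates, with Pearson r = 0.628 and Spearman rho = 0.621, and 65% had the same sign. Without U2 on array B, r was 0.58. Of 17 with a difference of at least 0.5 on array A, 16 had the same sign on array B. Within the array B station that held D1 to D3 and U1, r was 0.411, rho was 0.45, and 13 of the 17 had the same sign.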
